A study of Mus musculus with 2 samples.

How the data were processed

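Total RNA from C3H10T1/2 cells, a mouse embryonic mesenchymal line that can take on bone, fat and cartilage fates, was compared after infection with an empty vector or with a vector carrying Glis3, a zinc finger transcription factor of the Krüppel family. Per the series' design text, 1 pair of RNA samples was amplified into labelled cRNA and hybridised to 2 Agilent mouse oligonucleotide arrays with the dyes exchanged. On array 1 the Glis3 RNA carried Cy5 and the empty vector RNA Cy3, and on array 2 the reverse, per the labels. The arrays therefore measured the same RNA extracts, which count as 1 replicate. No test was possible, no p-value across genes is given, and the SD of the 2 arrays covers technical error only.

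The deposited scanner files hold 22393 spots each, of which 1075 are control spots that were left out. Per the file headers, they were written by Agilent Feature Extraction 7.5.1, and the series' text names version 7.5 with default parameters. The main value was the deposited log10 ratio of red over green, which the authors' software had computed after background subtraction from a fitted surface and an intensity-dependent dye normalisation. It was multiplied to the log2 scale, and the sign of array 2 was turned so that positive values mean higher with Glis3. The files also hold the authors' raw, background-subtracted and processed intensity of each channel, the software's p-value of each spot's log ratio, and flags for saturation, outliers and signal over background. The deposited series matrix holds a log10 value per spot that equals the ratio of processed signals, Glis3 over empty vector, within 0.001 on the log2 scale for 22393 of 22393 spots of each array. Its column medians were 0.0019 and -0.0016, so its scale and direction are settled by this match. It is uncentred. The genome build behind the probes is not given in the sources used here, so no coordinates are printed.

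Spots with an outlier flag on either array were removed, which concerned 19 spots on array 1 and 9 on array 2, and spots of the same probe were averaged. Probes were named through RefSeq accessions matched without versions to a table of the GRCm38.p6 assembly, or through a symbol or full name in the file's own description. Of 20868 probes, 10063 (48.2%) received a gene symbol, 44 of them from words in the description read by hand. The hand table covered members of the fixed lists and 5 genes looked up after their values were seen, namely Mest, Jag2, Lcn2, Scx and Ddit4l. The other 10805 probes kept the file's identifier. A gene with several probes was represented by its brightest probe, which left 20566 genes, identifiers included. The probes of Ccn2 differed. Its brighter probe read 1.22 and 1.36 on arrays 1 and 2, and its dimmer probe 0.19 and -0.05.

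A gene counted as measured when at least 1 group was well above background on both arrays. The size rule asked for at least 2-fold in the same direction on both arrays, with the channel of the brighter RNA well above background on both. As a yardstick, genes that passed the same limits in the direction of the dye, and so opposite ways between the groups, were counted too. Where the dimmer group was not well above background on either array, a lower bound is given. It set the bright group's mean against the mean of the higher of the lowest signal well above background and the dim probe's own signal, per channel after Aquantile normalisation in limma.

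Before the data were examined, 20 gene lists, the size rule and the rule for named genes were fixed. That rule took Glis3 first and then the 12 higher and 12 lower genes with the largest value on the weaker array, measured in both groups, not saturated and named by a symbol. It added up to 4 bounds each way, every gene past the rule in the osteoblast, adipocyte, FGF and hedgehog lists, up to 4 from each other list, and 8 genes fixed by name. Those 8 were Fgf18, Runx2, Spp1, Alpl, Bglap1, Pparg, Cebpa and Fabp4. No probe could be named Glis3, Runx2 or Bglap1 here, so these genes are not analysed here and the labels were not checked through the introduced gene. Each list's median log2 ratio was placed among 10000 random lists of the same size, matched on mean signal in 20 bins of measured genes. This percentile describes these extracts and is not a test.

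The scripts were tested on simulated data made from 18562 measured genes, with each array's noise drawn separately from genes not past the rule. Of 50 genes changed 4-fold, 100.0% were called in the right direction, of 50 changed 3-fold 94.0%, of 50 changed 2-fold 10.0% and of 50 changed 1.5-fold 0.0%. The changed genes were drawn from genes measured in both groups, so these shares do not cover genes measured in 1 group. None of 18362 unchanged genes passed, which covers independent noise and not a bias shared by the arrays. The unchanged genes gave 0 of dye-following sign, against 15 over all 20566 genes in the data, so the simulation did not reproduce those. Of 200 unchanged random lists of 20 genes, 4.0% fell outside the central 95% of random lists, and 100.0% of lists shifted by 0.3 lay above.

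The alternatives fixed beforehand were normexp background correction (offset 50) with loess, no background subtraction with loess, and median centring without loess. Others were the series matrix values, no filter or a stricter filter on dim probes, keeping flagged spots, the median over a gene's probes, each array alone, and other size rules. The other size rules were 1.5-fold, 3-fold, 2-fold for the mean of the arrays, and a software p-value under 0.01 on both arrays. After the data were seen, 3 more were added. These were centring on measured genes, removal of the median of the 15 by 15 spots around each spot (called the local median), and removal of medians of blocks of 15 rows by 22 columns. The block version was the first position correction tried. R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 were used.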

Results

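Gene expression was measured in C3H10T1/2 mouse mesenchymal cells infected with an empty vector or with Glis3, in 1 pair of RNA extracts on 2 dye-swapped arrays. The series' title places Glis3 in osteoblast and adipocyte differentiation, and the comparison asks which genes differed with the vector. Of 21318 spots, 19211 (Glis3) and 19367 (empty vector) were well above background on array 1, and 19341 and 19690 on array 2. Median raw signals were 168 and 160 on array 1 and 150 and 188 on array 2, over median local backgrounds of 46 to 52. Of 20566 genes, 18562 were measured and 17994 were measured in both groups on both arrays. With 1 extract per group the difference has no replicate check. Errors below are the SD of 2 arrays, which is technical, and the number of arrays limits the precision.

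The largest ratios belonged to Mest, an imprinted gene expressed from the paternal allele, and Dcpp1, a secreted protein gene known from salivary glands. Mest was 50.9-fold higher with Glis3, at a log2 ratio of 5.67 ± 0.15, and Dcpp1 was 53.9-fold higher, at 5.75 ± 0.40. A probe described by the file as LOC212871, similar to demilune cell and parotid protein, was higher by a log2 ratio of 5.44 ± 0.45. The file describes Dcpp1 by that same protein name, and whether the probes read separate transcripts was not tested. The LOC212871 probe lies outside the rule for named genes and is given after its value was seen. Rhox5, a homeobox gene on the X chromosome, was the lowest of the genes measured in both groups, 4.51-fold lower at -2.17 ± 0.17. With normexp and loess, and with loess without background subtraction, Mest read 4.56 and 4.37, LOC212871 4.15 and 3.94 and Rhox5 -1.35 and -1.23, all still past the rule.

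In all, 44 genes were higher and 14 were lower with Glis3 by at least 2-fold on both arrays, so that 75.9% of 58 genes were higher. Beside them, 15 genes passed the same limits in the dye's direction, against the 14 lower genes. None of the 15 was among the genes measured in both groups, where 39 were higher and 12 lower. At 3-fold on both arrays, 21 genes were higher, 2 lower and 0 dye-following. With normexp and loess, which draws dim spots toward 0, 22 higher and 3 lower genes passed. The 3 were Rhox5, Tnmd and Col9a1. A software p-value under 0.01 on both arrays held for 30 of the 44 higher and 8 of the 14 lower genes. Among the genes named below, it did not hold for Ahr, Epyc, Efemp1, Gbp3, Scx and Xlr, nor for Hhip, Jag2, Rnf128, Mark1 and Plxdc2.

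**Figure D1:**
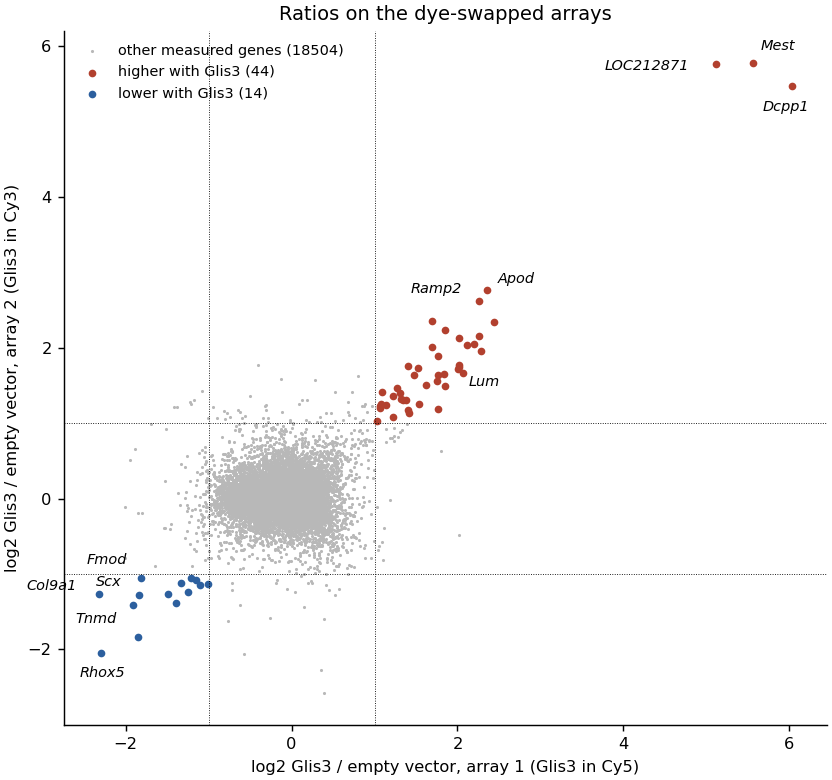
Each point is a measured gene, with its log2 ratio of Glis3 over empty vector on array 1 (x axis) and array 2 (y axis). Dotted lines mark 2-fold. Coloured points are the 44 higher and 14 lower genes, and Mest, Dcpp1 and LOC212871 stand apart at log2 ratios above 5.

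Across 18562 measured genes the arrays correlated at Pearson r = 0.149 and Spearman rho = -0.04, where genes are not independent replicates. Pearson r was -0.10 over the 4499 dimmest genes measured in both groups and 0.45 over the 4499 brightest. Spearman rho, which a few extreme genes move less, was -0.21 and 0.17 there. Of all measured genes, 47.3% had the same sign on both arrays. Array 1 carried a bias by position. The median of the 15 by 15 spots around a spot lay under -0.25 for 21.8% of its spots and for 0% of spots on array 2. Over 50 probes spotted up to 10 times, the median SD between spots was 0.238 on array 1 and 0.075 on array 2. Removing the local median, an alternative added after the data were seen, brought these to 0.076 and 0.053. It gave 46 higher, 14 lower and 9 dye-following genes, with 42 of the higher and 14 of the lower shared. C4b, a complement gene, went from 1.07 and 1.22 on arrays 1 and 2 to 0.98 and 1.20, and Osmr, the oncostatin M receptor, from 1.03 and 1.02 to 0.91 and 1.07. Both thus lay just under the limit on array 1 and no longer passed, and Dcn and Wnt5b newly passed. C4b and Osmr also did not pass with block medians removed, nor did Osmr with median centring. These 4 were named after their values were seen.

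**Figure D2:**
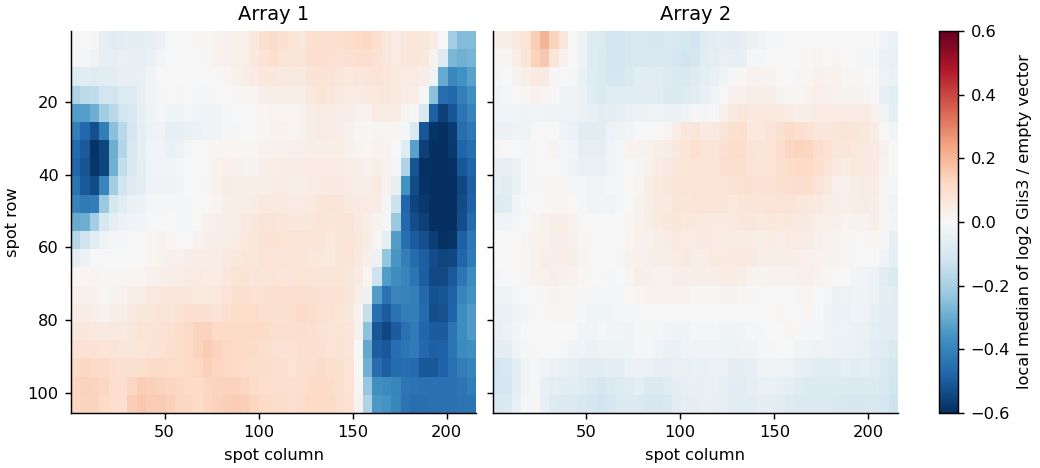
Local median of the log2 ratio of Glis3 over empty vector by spot column and row on each array, on 1 colour scale, shown as medians of tiles 5 spots wide. Array 1 holds a low region at its right edge and a smaller one at the left, and array 2 has no spot with a local median under -0.25.

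Apod, a lipocalin that binds lipids, was 5.90-fold higher (2.56 ± 0.29), and Ramp2, a partner of the calcitonin receptor-like receptor, 5.44-fold (2.44 ± 0.25). Igf1, a growth factor, was 4.62-fold higher (2.21 ± 0.07), and Lcn2, a lipocalin that binds siderophores, 3.71-fold (1.89 ± 0.17). Ahr, a ligand-activated transcription factor, was 4.22-fold higher (2.08 ± 0.06), and Epyc, a small leucine-rich proteoglycan, 3.69-fold (1.88 ± 0.19). Ahr, Lcn2 and Epyc no longer passed on both arrays with normexp and loess, at log2 ratios of 0.88, 1.06 and 0.75, with Lcn2 at 0.96 on array 2. Ramp2 read 1.46 there and 1.31 without background subtraction, and Igf1 1.60 and 1.5, and both still passed. For 4 named genes the empty vector group was not well above background on either array. Hhip was at least 2.67-fold higher, Jag2, a Notch ligand, at least 2.49-fold, Rnf128, a ubiquitin ligase, at least 2.21-fold, and Mark1, a kinase, at least 2.07-fold. These bounds rest on genes dim in the other group. All 15 dye-following genes lay among genes not measured in both groups, which also include genes not measured at all. None of the 4 passed with normexp and loess, at log2 ratios of 0.34, 0.42, 0.28 and 0.29, far under the bounds.

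Among the lower genes, Tnmd, a membrane protein of tendon and ligament, was 3.16-fold lower (-1.66 ± 0.35). Scx, a transcription factor of tendon progenitors, was 2.94-fold lower (-1.56 ± 0.40). Hsd11b1, which regenerates active glucocorticoid, was 2.18-fold lower (-1.12 ± 0.03), and Xlr, an X-linked lymphocyte-regulated gene, 2.17-fold lower (-1.12 ± 0.06). Plxdc2, a plexin domain protein not well above background with Glis3, was at least 3.11-fold lower. With the local median removed, Tnmd read -1.53 and -1.44 and Scx -1.44 and -1.22 on arrays 1 and 2. Scx, Hsd11b1, Xlr and Plxdc2 no longer passed with normexp and loess, at log2 ratios of -0.76, -0.95, -0.64 and -0.34.

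**Figure D3:**
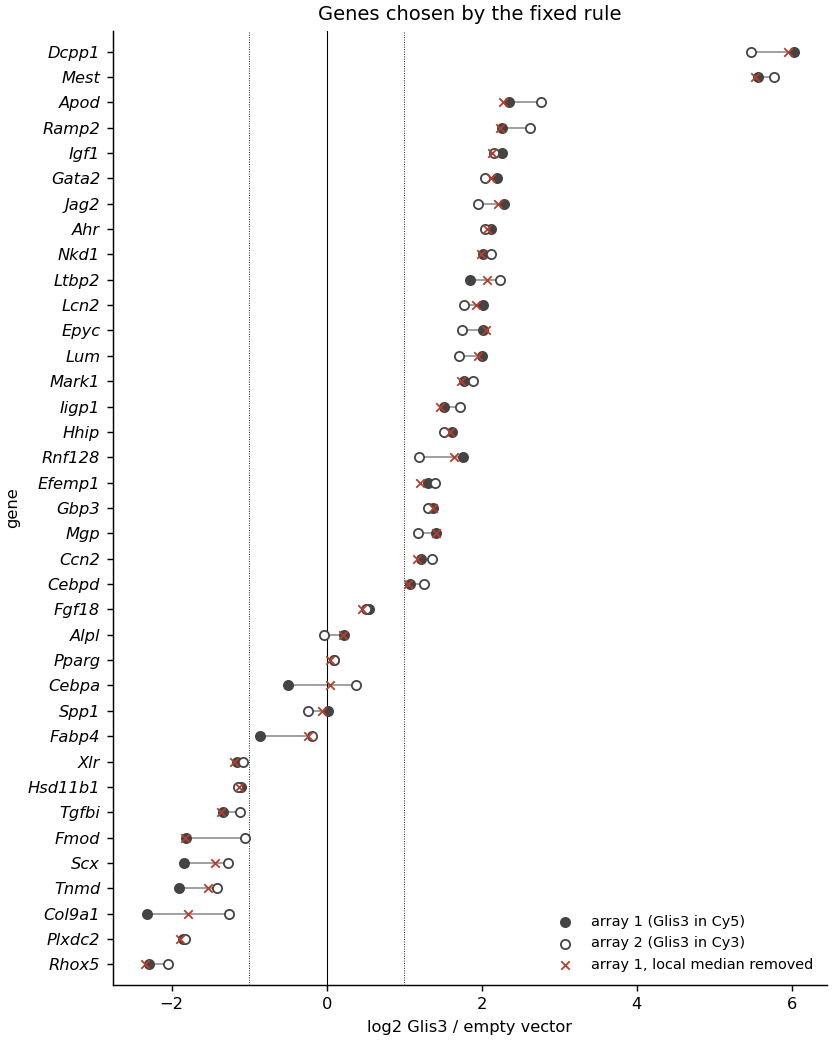
Log2 ratio of Glis3 over empty vector (x axis) for the genes chosen by the fixed rule (y axis), on array 1 (filled) and array 2 (open), with array 1 after removal of the local median as crosses. Dotted lines mark 2-fold. Fabp4 moved from -0.85 to -0.24 and Cebpa from -0.50 to 0.05 on array 1.

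Bone marker genes did not pass the size rule. Of 20 measured osteoblast genes, 0 were higher and 0 lower, with a median log2 ratio of 0.040 at the 90.9th percentile of random lists, and of -0.003 at the 46.3rd with the local median removed. Spp1, which encodes osteopontin, read 0.02 and -0.24 on arrays 1 and 2, and Alpl, the bone alkaline phosphatase, 0.23 and -0.03. Alpl was dim, at a mean log2 signal of 7.33. It lay among the 4499 dimmest genes measured in both groups, where Pearson r of the arrays was -0.10. Phex, an endopeptidase gene of osteoblasts, read 1.19 and 0.81, and passed at 1.5-fold and on array 1 alone. It was chosen after its values were seen.

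Of 25 measured adipocyte genes, 2 were higher and 0 lower. Gata2, a transcription factor that restrains fat cell formation, was 4.36-fold higher (2.12 ± 0.11), and Cebpd, an early adipogenic factor, 2.24-fold (1.17 ± 0.12). Gata2 still passed at 1.58 with normexp and loess and at 1.47 without background subtraction. Pparg, the central regulator of adipocyte fate, read 0.10 on both arrays. Cebpa, which acts with it, read -0.50 and 0.39, and Fabp4, a fatty acid binding protein of adipocytes, -0.85 and -0.19. Cebpa, at a mean log2 signal of 7.98, also lay among the 4499 dimmest genes measured in both groups. Adipoq, also in the list, read 0.52 and 1.41, past 2-fold on array 2 only, and was named after its values were seen. As deposited, 12 of the 25 genes were above 0 and 13 below. With the local median removed, array 1 gave 0.05 for Cebpa and -0.24 for Fabp4. The list median was -0.040 at the 14.3rd percentile. It turned to 0.028 at the 89.9th percentile with the local median removed, to 0.006 with normexp and loess, and to 0.097 on array 2 alone.

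FGF ligands and receptors gave 0 higher and 0 lower of 23 measured genes. Fgf18, a growth factor of bone and cartilage, was 1.44-fold higher at 0.53 ± 0.03, under the size rule. The list median was 0.025, at the 78.8th percentile, and that of 12 feedback genes of the FGF and ERK pathway was 0.057, at the 94.9th. Of 15 hedgehog and Gli genes, Hhip, a membrane inhibitor of hedgehog ligands, was higher and 0 were lower. Gli1 read 0.21 and 0.43, and Ptch1, the hedgehog receptor, 0.08 and -0.21, both named after their values were seen. That list's median was 0.015, at the 67.1st percentile. With the local median removed the hedgehog median turned to -0.015, the FGF median was 0.009, and the feedback median was 0.003, at the 58.4th percentile.

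Matrix genes leaned toward higher values. Of 40 measured, 3 were higher and 1 lower, and the median of 0.159 had 0 of 10000 random lists above it, as did the median of 0.116 with the local median removed. It lay between 0.050 and 0.167 over the 14 settings run for lists, with the lowest value from loess without background subtraction and 0.061 with normexp and loess. Lum, a collagen-binding proteoglycan, was 3.62-fold higher (1.86 ± 0.21). Efemp1, a fibulin, was 2.56-fold higher (1.35 ± 0.06) and Mgp, an inhibitor of calcification, 2.45-fold (1.29 ± 0.16). Fmod, another collagen-binding proteoglycan, was 2.70-fold lower (-1.43 ± 0.54). Dcn read 0.80 and 1.62, with 1.41 on array 1 after removal of the local median, and was chosen after its values were seen. Efemp1 and Fmod no longer passed with normexp and loess, at 0.46 and -1.27, with Fmod at -1.64 on array 1 and -0.91 on array 2.

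The BMP and TGF-beta list held 2 higher and 1 lower of 34 genes. Ltbp2, a microfibril protein of the latent TGF-beta binding protein family, was 4.11-fold higher (2.04 ± 0.27), and Ccn2, a matricellular protein, 2.45-fold (1.29 ± 0.10). With the median over a gene's probes Ccn2 read 0.68 ± 0.04 and did not pass, because its dimmer probe read 0.19 and -0.05. Tgfbi, a matrix protein induced by TGF-beta, was 2.33-fold lower (-1.22 ± 0.15). Tgfbi no longer passed with normexp and loess, at -0.99 with -0.91 on array 2, nor without background subtraction, at -0.94. The list median was -0.024, at the 21.9th percentile, and lay between -0.113 and -0.013 over the 14 settings. Of 41 Wnt genes, Nkd1, an intracellular inhibitor of the pathway, was 4.21-fold higher (2.07 ± 0.07), and 0 were lower. Nkd1 still passed at 1.32 with normexp and loess and at 1.21 without background subtraction. Sfrp1, a secreted Wnt binder, read 0.86 and 1.04 and did not pass, and was named after its values were seen. The Wnt median was 0.056, at the 99.4th percentile, and lay between 0.017 and 0.081 over the 14 settings.

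Interferon and antiviral genes had the highest median of the fixed lists, 0.251 over 22 genes with 0 of 10000 random lists above it, and 2 were higher and 0 lower. Iigp1, an interferon-inducible GTPase, was 3.08-fold higher (1.62 ± 0.14) and Gbp3, a guanylate-binding protein, 2.54-fold (1.35 ± 0.05). With normexp and loess Iigp1 read 1.03 and passed, and Gbp3 read 0.40. Without background subtraction Iigp1 read 0.93 and Gbp3 0.35, so that neither passed. Psmb8, an immunoproteasome subunit, read 0.97 and 1.23, just short of the rule, and was named after its values were seen. The median lay between 0.106 and 0.354 over the 14 settings. Of 30 cell cycle genes 0 passed the rule, and the median was -0.193, with 1 of 10000 random lists below it. It lay between -0.267 and -0.160 over the 14 settings, and was -0.148 on array 1 alone with the local median removed. As deposited, 23 of 30 genes were below 0.

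Of 15 chondrocyte genes, 1 was lower and 0 higher. Col9a1, a cartilage collagen chain, was 3.46-fold lower (-1.79 ± 0.75), reading -2.32 and -1.26. The list median of -0.308 had 0 of 10000 random lists below it. It was -0.416 on array 1 and -0.029 on array 2, and -0.067 at the 0.9th percentile with the local median removed. Col9a1 read -1.79 on array 1 after that removal, and -1.37, no longer past the rule, with loess without background subtraction.

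Lists of other cell types held no gene past the rule. The medians were -0.015 for 17 skeletal and smooth muscle genes, -0.025 for 7 macrophage markers, -0.029 for 7 endothelial markers and -0.076 for 8 epithelial markers. They lay at the 36.8th, 34.9th, 29.3rd and 18.4th percentiles. The remaining lists also had 0 genes past the rule. Their medians were 0.002 for 25 matrix proteases and inhibitors, -0.025 for 32 chemokines and cytokines and 0.005 for 18 stress genes. They were 0.003 for 20 genes of islet, thyroid and kidney and -0.014 for 11 housekeeping genes, and percentiles ranged from 24.1 to 58.4. Over the 14 settings the medians of all these lists lay between -0.113 and 0.114.

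**Figure D4:**
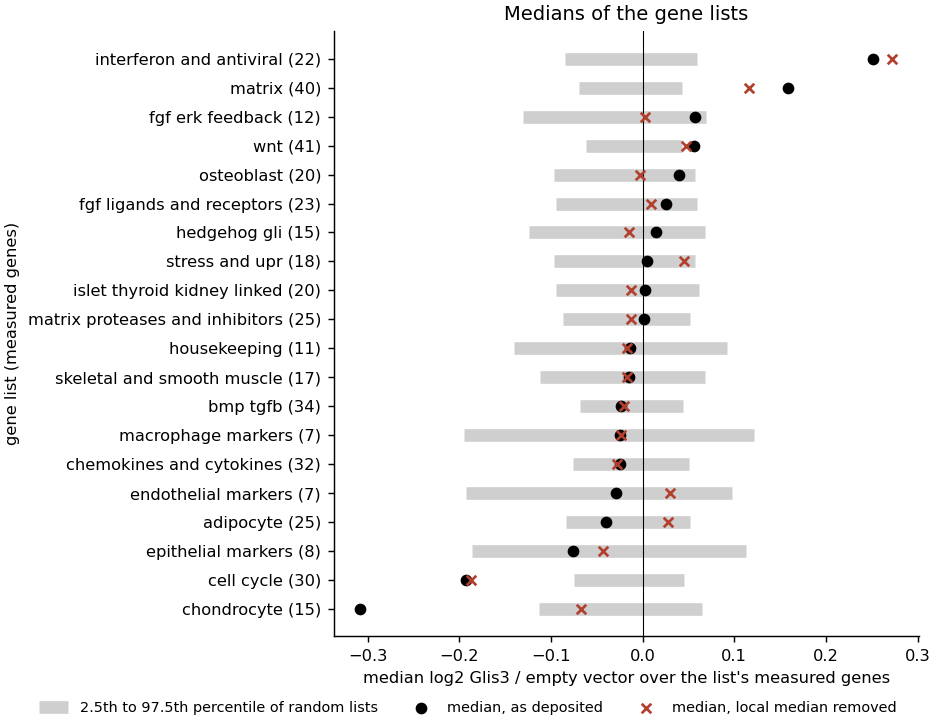
Median log2 ratio of Glis3 over empty vector (x axis) for each fixed gene list (y axis, with its number of measured genes), as deposited (dots) and with the local median removed (crosses). Grey bars span the central 95% of random lists matched to the deposited values. The deposited medians of the interferon (0.251), matrix (0.159), Wnt (0.056), cell cycle (-0.193) and chondrocyte (-0.308) lists lie outside them.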

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

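The position corrections (local median, block medians), the centring on measured genes and the pairing of the local median with a left-out array were chosen after seeing the data, and the other settings were planned. Higher and lower counts of 44 and 14 became 22 and 3 with normexp and loess, and 19 and 2 with loess without background subtraction, where dye-following genes fell from 15 to 0. Those settings add signal to dim spots, which shrinks their ratios. Correlations of the arrays, given here as Pearson r, were then 0.241 and 0.222 against 0.149. Median centring without loess gave 42 dye-following genes and a correlation of 0.085. Without a filter on dim probes there were 27 dye-following genes at a correlation of -0.002, and with both groups well above background 0 at 0.199. The local median left 9 dye-following genes at 0.196, and block medians gave 0.178. Spearman rho was -0.09 with the local median removed against -0.04 as deposited, so the ranks of genes did not come closer between arrays. Keeping flagged spots gave 0.146, and the median over probes 0.147. At 1.5-fold there were 107 higher, 50 lower and 121 dye-following genes, with 1 osteoblast gene. At 3-fold there were 21, 2 and 0, with 1 adipocyte gene. The mean of the arrays gave 60 higher, 23 lower and 44 dye-following genes. The software p-value gave 80, 40 and 8, with only 30 of the 44 higher and 8 of the 14 lower genes among them. Apart from the looser or stricter limits themselves, the cause of these other shifts was not tested.

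Higher genes ranged from 63 to 87 and lower genes from 38 to 116 with either array left out. Array 1 alone gave 63 higher and 116 lower, so that 35.2% were higher, against 69.6% on array 2 alone. With the local median removed as well, array 1 alone gave 66 and 33 (66.7% higher) and array 2 alone 88 and 40, so the reversed split on array 1 went with its position bias. Over the 14 settings run for lists, the osteoblast median ranged from -0.016 to 0.056, with 0 to 1 genes past the rule, and the adipocyte median from -0.044 to 0.097. The ends at -0.016 and 0.097 came from array 2 alone. With the local median removed as well, the osteoblast median was -0.018 on array 2. The dye-following count and the correlation have no value with 1 array. No gene named Glis3 was found, so that planned value was not run. Of the 37 named genes, 26 moved by 1 SD of the arrays or more under at least 1 alternative. None with a call changed sign, but calls required the same direction on both arrays, so settings such as either array alone could not turn it. No paired analysis was possible because both arrays hold the same pair of RNA extracts. Signal over background limits the dim genes, whose ratios differed by a median of 0.309 between arrays over the 4499 dimmest genes measured in both groups and 0.175 over the 4499 brightest.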

Other observations

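The lists of acute phase and complement, imprinted and tendon genes were written after the genes past the rule were seen, so their counts and whole-list medians are not independent evidence. Of 23 measured acute phase and complement genes, 6 were higher with Glis3 and 0 lower. These were Lcn2, Hp, a haemoglobin-binding plasma protein, Lbp, which binds lipopolysaccharide, Cebpd, C4b and Osmr, the oncostatin M receptor. Hp was 3.61-fold higher (1.85 ± 0.22, SD of 2 arrays) and Lbp 2.38-fold (1.25 ± 0.23). The median of all 23 was 0.422, but it includes the 6 genes seen before the list was written, so it is not ranked against the fixed lists. With the local median removed, the median of the list was 0.196 on array 1 and 0.647 on array 2. With normexp and loess only Hp (1.34) and Cebpd (1.13) passed, while Lcn2 read 1.06 (0.96 on array 2), Osmr 0.84, Lbp 0.74 and C4b 0.73. Without background subtraction Hp read 1.24. The other 17 had a median log2 ratio of 0.043, at the 90.8th percentile of random lists, and 0.071 at the 98.5th with the local median removed. Serpina3n read 0.85 and 0.86, and Socs3, a feedback inhibitor of cytokine signalling, 0.72 and 0.87, and both were named after their values were seen. With the local median removed C4b went from 1.07 and 1.22 to 0.98 and 1.20 and Osmr from 1.03 and 1.02 to 0.91 and 1.07, so both lay just under the limit on array 1 and no longer passed. Of 13 imprinted genes, Mest was higher and 0 were lower, and the other 12 had a median of 0.032, at the 78.9th percentile, and 0.012 at the 63.4th with the local median removed.

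The tests on dye bias and spot noise, on position, on random lists trimmed like the tendon list and on the genes flanking the X-linked pair were chosen only after the results were seen, and those on the scale offset, the other tendon genes, the X chromosome and the order of genes before.

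More genes were higher than lower, 44 against 14. Against dye bias and spot noise as the cause of the whole, genes past the rule were 3.87 times as many as dye-following genes, and 0 dye-following genes were among those measured in both groups, against 51 past the rule. For the 7 genes measured in 1 group, a dye effect alone would turn sign between the swapped arrays, so the rule itself leaves it out without a separate test. Spot noise, alone or on top of a dye effect, stays open there. All 15 dye-following genes lay among genes not measured in both groups, a set wider than the genes measured in 1 group. An offset of the log ratio scale cannot be told apart, since centring moved the arrays by only -0.0035 and -0.0021 and left 75.9% higher, and dye normalisation would hide a true offset. A response to Glis3 stays open and untested with 1 extract per group.

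Scx, Tnmd and Fmod, genes of tendon, were all lower. The median of all 19 measured tendon-list genes was 0.061 with 253 of 10000 random lists above it. It was -0.027 at the 36.3rd percentile on array 1 and 0.123 at the 99.2nd on array 2. With the local median removed it was 0.014 at the 72.8th percentile, so the list as written did not lie below random lists. Without the 3, the median was 0.127, and 0.096 with the local median removed. These lay at the 99.8th and 99.1st percentiles of random lists that also lost their 3 lowest genes (the first at 99.99 against whole random lists, which favours the trimmed list). Of the 19, 11 also stand in the matrix list, which leaned higher with a median of 0.159. Of the other 16 tendon-list genes, 11 read above 0. These values argue against lower expression over the tendon list as written. Given the shared genes, they cannot separate tendon from matrix genes and do not decide on genes particular to tendon. Dye bias and spot noise as the cause of all 3 are argued against only by the count given above, 0 dye-following genes among those measured in both groups. Position on array 1 is argued against by the values there after the local median was removed, -1.53 for Tnmd, -1.44 for Scx and -1.83 for Fmod. The smallest decrease on either array was then -1.10, for Fmod on array 2. A lower level of these 3 genes in the Glis3 culture is a hypothesis, and with normexp and loess Scx went from -1.56 to -0.76 and Fmod from -1.43 to -1.27 (-0.91 on array 2), so neither passed.

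Tnmd and its neighbour Tspan6 on the X chromosome (gene order of GRCm38.p6) were both lower, with Tspan6 at -1.15 and -0.70, and at -0.80 and -0.70 with the local median removed, so short of the rule on array 2 and then on both. Loss of chromosome copies in 1 culture is argued against by 307 other measured genes of the X chromosome, with a median of -0.014. Neighbouring genes across the genome did resemble each other slightly, at a correlation of 0.044 over 8777 pairs against at most 0.031 in 1000 shuffles (0.050 without genes past the rule, and 0.070 with the local median removed), as a regional change over many genes would give. At this pair, though, the 5 measured genes on each side had a median of 0.066 and lay between -0.249 and 0.181, which argues against a change reaching beyond the pair. Why the pair moved together was not tested further.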
